A study of Arabidopsis thaliana with 6 samples.

How the data were processed

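RNA from 3-week-old whole Arabidopsis thaliana plants was measured on NimbleGen arrays with 1 colour (Cy3), with 3 samples per group and 1 array per sample. The groups were taken from the labels, which name the construct and the line of each sample. The labels call the 3 samples of a group biological replicates from separate cultures, so p-values measure the spread between samples of separate lines. With 1 array per line, differences between lines, cultures and arrays cannot be told apart in this spread. By their array names all 6 arrays lay on 1 slide and were scanned together, so there was no slide or scan batch to block. The empty vector samples lay at positions 3, 4 and 10 and the MYBPAR samples at positions 5, 7 and 8. Position on the slide was not modelled.

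The deposited intensity values are RMA expression values on a linear scale, 1 per feature and array, per the file headers and the submitters' processing notes, which name RMA. RMA corrects background, normalizes by quantiles between arrays and summarises the probes of a feature. Its software version, its background model and the annotation behind the probe design are not given in the sources used here. Features had 1 to 4 probes, and 26409 of 37118 had 4. The deposited log2 values of the series table equalled log2 of these intensities to within 1.66e-06, so they have the same scale and are not centred. A column of standard errors in the sample files, whose meaning is not stated, was not used. Quantile normalization holds the distribution of values equal between arrays, so a shift of most transcripts in one direction would not be seen.

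Locus identifiers come from the features. Of 32627 loci, 31993 matched a locus tag in the RefSeq gene table of assembly TAIR10.1, which was used for names only, and 634 did not and keep their identifier. No coordinates are given because the sources used here name no genome build for the arrays. A gene whose list name was not in that table is printed by its locus identifier.

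Values were tested as log2 of the deposited intensities with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with no trend and not robust), as MYBPAR minus empty vector over all 6 arrays, with no filter and no covariate. Adjusted p-values are Benjamini-Hochberg values over all 37118 features with a threshold of 0.05, and intervals are 95% intervals of the moderated fit, not adjusted for the number of features. Given in the text as log2 differences, the values are differences of group means. An exact permutation test of 3 against 3 samples cannot go below p = 0.1, so single genes rest on the limma model. The 22 gene lists (216 entries written from textbook knowledge before the data were examined) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists. Camera was also run with an estimated correlation, and fry as another set test; fry's directional p asks whether the genes of a list move one way on balance and does not compare a list with other genes. A locus with several features was represented in lists by the feature with the highest mean.

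The genes named in the text were set by a rule before the data were examined. It takes all members of the proanthocyanidin branch, early flavonoid and regulator lists. It takes the 12 largest changes in each direction among features past the threshold whose groups do not overlap, or the 6 smallest p as values where none passes. From each other list it takes up to 4 members past the threshold, or the 1 member with the smallest p as a value. FLS1, GSTF5 and the clock, floral and other genes of the lists added later were chosen after values were seen. The added lists hold floral organ identity, anther, ovule and seed coat, touch and cold, and clock genes; the flower list shares all 7 organ identity genes, and the regulator list shares TT2, TT1 and TT16 with the ovule list.

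The model was tested on simulated data with 200 of 37118 features changed, 20 times, for MYBPAR against empty vector with 3 against 3. It recovered 32.7% of features changed by 1 on the log2 scale, 84.7% of those changed by 2 and 97.6% of those changed by 4, and 5.29% of its calls were false. The simulated noise was independent between features, with the moderated variances, and changes were planted only in features with lower control means. The real arrays share structure across features, so these rates need not hold for them. The arrays carry no counts or depth, so precision is limited by the number of arrays. The minimum between the low and high modes, at a log2 value of 7.12, was taken from a density estimate of the mean log2 values and served for bounds on folds and to say which genes lie in the low mode.

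The alternatives were another quantile normalization, centring on array medians, the series table, eBayes with trend and robust, no moderation, leaving out the dimmest 25% of features, log2(value + 32), array weights, the replicate number as a block, means over the features of a locus, a minimum log2 change of 1, a threshold of 0.1, and leaving out each sample. Added after the data were seen were a floral covariate, a clock covariate and the proanthocyanidin list without BAN, or without both BAN and AHA10. The floral covariate is the mean of the 7 organ identity genes. The clock covariate is the mean of CCA1, LHY and PRR9 minus the mean of TOC1, ELF4, LUX and GRP7.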

Results

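Whole-plant RNA was compared between 3 independent Arabidopsis thaliana lines that carried 35S::VvMYBPAR and 3 independent lines transformed with an empty vector. VvMYBPAR is a MYB transcription factor of grapevine, and the 35S promoter of cauliflower mosaic virus drives expression throughout the plant. The design asked which Arabidopsis transcripts differ when the grapevine factor is expressed constitutively. All plants were of the Columbia ecotype, were 3 weeks old and had grown on agar with 30 mg/l kanamycin under 16 h of light per day at 22 °C. Each line gave 1 RNA sample on 1 single-colour array, and the labels describe the 3 samples of a group as separate cultures. The lines are called MYBPAR replicates 1 to 3 and empty vector replicates 1 to 3.

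Each array held 37118 features for 32627 loci, and the features carry Arabidopsis locus identifiers, so the introduced grapevine transcript itself was not read here. Median RMA values lay between 859 and 887 intensity units on all 6 arrays. The mean log2 values of the features formed a low and a high mode with a minimum between them at 7.12, and 33.0% to 33.4% of the features of an array lay below that minimum. Pearson's r across features was 0.987 to 0.991 between MYBPAR arrays, 0.989 to 0.993 between empty vector arrays and 0.984 to 0.993 between arrays of different groups. Features are not independent replicates. The number of arrays, 3 per group, limits the precision of every comparison below.

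The arrays also differed in ways that the groups did not define. The morning-expressed clock genes CCA1, LHY and PRR9 had log2 values of 7.54, 7.53 and 7.19 in MYBPAR replicate 2. On the other 5 arrays they lay between 11.62 and 13.50 for CCA1, between 9.83 and 13.04 for LHY and between 11.55 and 12.64 for PRR9. The evening-expressed clock gene ELF4 ranged from 8.43 in empty vector replicate 3 to 13.20 in MYBPAR replicate 2. The mean of 7 floral organ identity genes (AP1, AP3, PI, AG, SEP1, SEP2 and SEP3), relative to the mean of the empty vector arrays, was -0.75 in empty vector replicate 1, 0.04 in replicate 3 and 0.71 in replicate 2, against 0.18, 0.93 and 1.04 in MYBPAR replicates 1, 2 and 3. The clock genes and the organ identity list were chosen after values were seen.

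**Figure D1:**
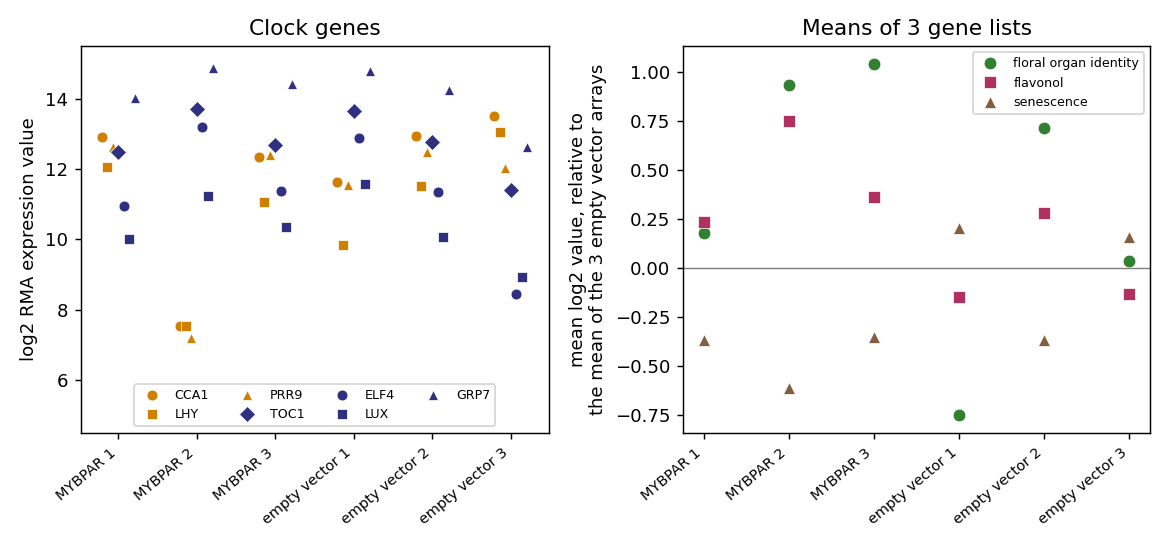
Left, log2 RMA expression values of 7 clock genes on each array (y axis), with morning-expressed genes in orange and evening-expressed genes in blue. CCA1, LHY and PRR9 lie at 7.54, 7.53 and 7.19 in MYBPAR replicate 2, below all other arrays. Right, mean log2 value of 3 gene lists per array relative to the mean of the 3 empty vector arrays (y axis, log2 units), with 1 point per list and array.

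BAN and AT2G38900 rose in the MYBPAR lines, and no other feature passed the test across all features. BAN encodes anthocyanidin reductase, the enzyme that makes the epicatechin units of proanthocyanidins (condensed tannins). Its log2 value was 10.92 ± 0.68 (SD, n = 3) in the MYBPAR lines and 4.71 ± 0.05 (SD, n = 3) in the empty vector lines. The log2 difference was 6.21 (SE 0.33, lower 95% bound 5.42; limma, Benjamini-Hochberg adjusted p = 0.0283). AT2G38900, annotated as a serine protease inhibitor of the potato inhibitor I type, had 9.67 ± 0.70 (SD, n = 3) against 3.84 ± 0.08 (SD, n = 3). Its log2 difference was 5.83 (SE 0.34, lower 95% bound 5.01; limma, adjusted p = 0.0283).

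All 3 control values of both genes lay in the low mode, where an array signal may be background, so a fold is given as a bound. With each control value raised to the minimum between the modes, BAN was at least 13.9-fold higher and AT2G38900 at least 5.85-fold higher. This bound was chosen after the values were seen, and the files used here carry no detection call. In MYBPAR replicates 1, 2 and 3, BAN reached 11.69, 10.63 and 10.43, and AT2G38900 reached 10.43, 9.52 and 9.05.

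**Figure D2:**
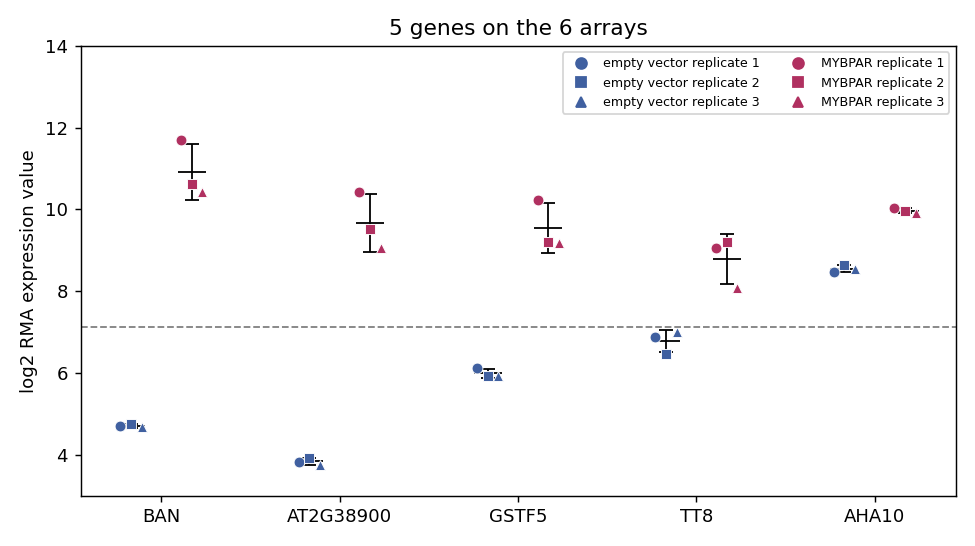
Log2 RMA expression values (y axis) of 5 genes (x axis) on the 3 empty vector arrays (blue) and the 3 MYBPAR arrays (red), with 1 symbol per array and black bars for the mean ± SD of each group. The dashed line marks the minimum between the low and high modes at 7.12. For all 5 genes the 3 MYBPAR values lie above the 3 empty vector values, and only BAN and AT2G38900 passed the test across all features.

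The next features by p did not pass across all features. AHA10, a proton pump of the vacuolar pathway of seed coat tannins, had a log2 difference of 1.42 (SE 0.10; limma, adjusted p = 0.0794), with 9.97 ± 0.06 (SD, n = 3) against 8.55 ± 0.09 (SD, n = 3). GSTF5, a phi-class glutathione S-transferase named after its values were seen, had a log2 difference of 3.55 (SE 0.30; limma, adjusted p = 0.134), and as its controls lay in the low mode it was at least 5.37-fold higher by the same bound. At the looser threshold of 0.1, 3 features were higher and 0 were lower. Limma gave 893 features higher and 709 lower at an unadjusted p under 0.05, in total 1602 where 1856 of 37118 would be reached by chance alone. In 9.99% of the features the 3 values of one group lay entirely on one side of the other group's, where chance gives 10%.

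The call of both genes changed with the samples and with the estimate of the spread. Leaving out MYBPAR replicate 2 or 3 or any 1 of the 3 empty vector replicates gave 0 calls, with an adjusted p for BAN of 0.385, 0.0562, 0.220, 0.316 and 0.545 in that order, while its log2 difference stayed between 5.82 and 6.45 over all 6 fits that left out 1 sample. Without MYBPAR replicate 1, 3 features were called. A linear model with no moderation across features also gave 0 calls, and with log2(value + 32) AT2G38900 missed the threshold (adjusted p = 0.0954) while AHA10 passed it (adjusted p = 0.0415).

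No feature fell in the MYBPAR lines in the limma test, and the smallest adjusted p in this direction was 0.915. The linear model with no moderation also gave 0. By the rule fixed in advance, the 6 features with the smallest p are given as values. AT1G56660 had a log2 difference of -0.98 (SE 0.20), AT4G15990 of -0.94 (SE 0.15) and AT1G38194, listed as a pseudogene, of -0.79 (SE 0.13). AT3G11920, with both means in the low mode, had -0.79 (SE 0.14), AT4G39360 -0.76 (SE 0.11) and EXLA2, an expansin-like gene, -0.53 (SE 0.11).

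The proanthocyanidin branch list rose as a group. It holds the enzymes, transporters and other genes that act on the way from dihydroflavonols to seed coat tannins, and all 9 members had log2 differences above 0, with a median of 0.47. Camera with its preset correlation gave an adjusted p of 1.05e-06 over 22 lists. With an estimated correlation, -0.06 for this list, camera gave an adjusted p of 0.105. That estimate lay below the preset correlation, so stronger correlation between the members does not account for the higher adjusted p. What else in this setting raised it was not tested. Across all features 1 member passed, BAN, and 3 passed when adjusted over the list alone, namely BAN (adjusted p = 7.57e-06), AHA10 (adjusted p = 2.89e-05) and TT10 (adjusted p = 0.0329), all limma. TT10, a laccase-type oxidase of seed coat flavonoids, had a log2 difference of 0.78 (SE 0.22).

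The other 6 members passed neither way. DFR and LDOX, the enzymes that lead to anthocyanidins, had log2 differences of 0.40 (SE 0.24) and 0.47 (SE 0.20). The vacuolar transporter gene TT12 had 0.52 (SE 0.42) with both group means in the low mode, at 6.08 and 5.56. The glutathione transferase gene TT19 had 0.07 (SE 0.22), TT15 0.16 (SE 0.20) and TT9 0.04 (SE 0.13). Without BAN, an alternative added after the data were seen, the median of the remaining 8 was 0.43 (camera, adjusted p = 5.94e-04), and the adjusted p was 0.274 with an estimated correlation. Without BAN and AHA10, also added after the data were seen, the median of the remaining 7 was 0.40 (camera, adjusted p = 0.0271). The list of 9 was called in each of the 6 fits that left out 1 sample, with the lowest median, 0.30, without MYBPAR replicate 2. With the mean of the 7 floral organ identity genes as a covariate, added after the data were seen, its median was 0.25 (camera, adjusted p = 7.53e-04).

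**Figure D3:**
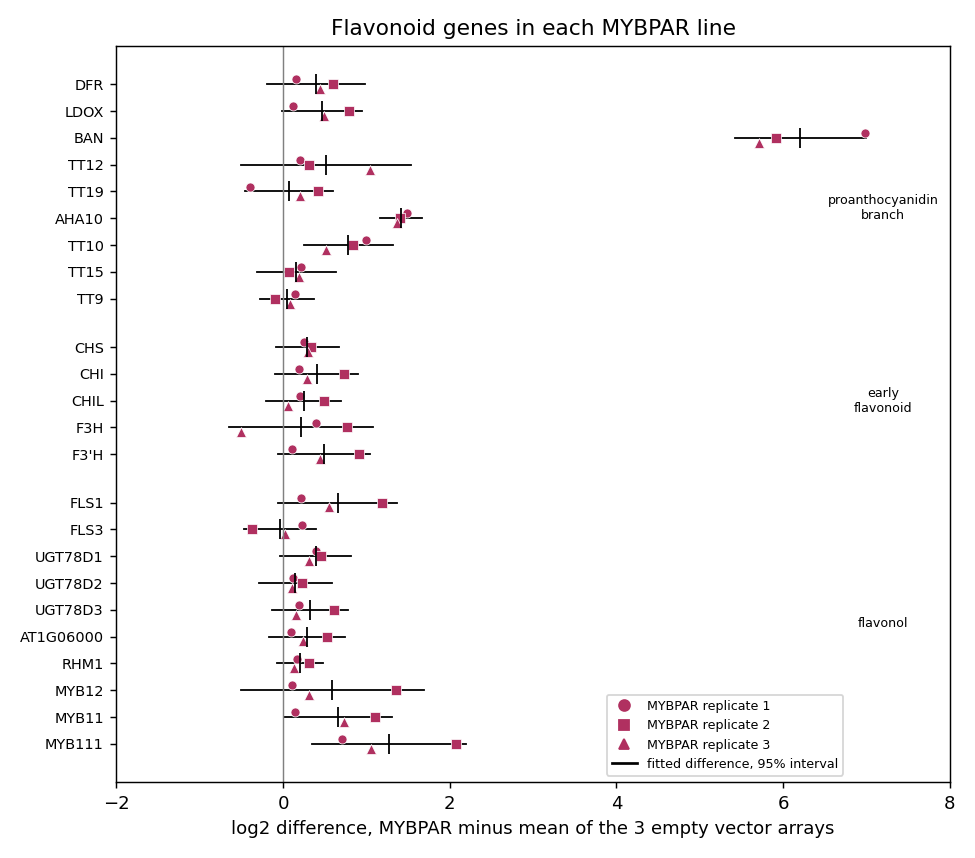
Log2 difference of each MYBPAR line from the mean of the 3 empty vector arrays (x axis, 1 symbol per line) for the genes of 3 flavonoid lists (y axis), with the fitted difference and its 95% interval in black. BAN lies at 6.21 and AHA10 at 1.42, and the symbols of MYBPAR replicate 2 lie farthest right for all genes of the early flavonoid and flavonol lists except FLS3.

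The flavonol and early flavonoid lists were called higher as groups, with smaller differences and no member past the threshold across all features or adjusted over the list alone. In the flavonol list 9 of 10 members had log2 differences above 0, and the median was 0.35 (camera, adjusted p = 5.94e-04). With its estimated correlation of 0.50, camera gave an adjusted p of 0.534. MYB111, a regulator of flavonol synthesis, had 1.28 (SE 0.38), and FLS1, flavonol synthase, had 0.65 (SE 0.30). In the early flavonoid list all 5 members were above 0 with a median of 0.29 (camera, adjusted p = 0.0271). With its estimated correlation of 0.66, camera gave an adjusted p of 0.650. Chalcone synthase (CHS) had 0.29 (SE 0.16), chalcone isomerase (CHI) 0.40 (SE 0.21), CHIL 0.25 (SE 0.18) and F3'H 0.49 (SE 0.23). The feature of F3H stood at 4.58 and 4.37 in the groups, in the low mode, with a log2 difference of 0.22 (SE 0.36).

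The flavonol list mean, relative to the empty vector arrays, was highest at 0.75 in MYBPAR replicate 2, the array with the low morning clock genes, and was 0.24 and 0.36 in replicates 1 and 3, against 0.28 in empty vector replicate 2. Without MYBPAR replicate 2 the flavonol median was 0.19 (camera, adjusted p = 0.00281). Empty vector replicate 1, whose clock score (mean of CCA1, LHY and PRR9 minus mean of TOC1, ELF4, LUX and GRP7) of -2.22 was the second-lowest, had the lowest flavonol and early flavonoid means, at -0.15 and -0.28, and empty vector replicate 3, with the highest score of 2.51, had -0.13 and 0.20. With the clock score as a covariate, also added after the data were seen, both lists were called, with medians of 0.21 for flavonol (camera, adjusted p = 0.00131) and 0.33 for early flavonoid genes (adjusted p = 0.0362). With the floral covariate the median was 0.15 for the flavonol list (camera, adjusted p = 0.246) and 0.19 for the early flavonoid list (adjusted p = 0.438). Without empty vector replicate 1 neither list was called (medians 0.26 and 0.14, camera, adjusted p = 0.0739 and 0.271). The early flavonoid list was not called either without MYBPAR replicate 1 (median 0.31, adjusted p = 0.0568) or 2 (median 0.24, adjusted p = 0.115). It was called in 3 of the 6 fits that left out 1 sample, with the highest median, 0.46, without MYBPAR replicate 3.

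The regulator list holds MYB, bHLH and WD40 genes and other regulators, activators and repressors together. It was not called as a group (camera, adjusted p = 0.107), with 13 of 22 members above 0 and a median of 0.14. Camera called it without MYBPAR replicate 2 (median 0.10, adjusted p = 0.0127) and without empty vector replicate 3 (median 0.21, adjusted p = 0.0301). Without empty vector replicate 1 its median was -0.04 (camera, adjusted p = 0.499). Fry's mixed test, which ignores direction and does not compare a list with other genes, gave an adjusted p of 0.0461. TT8, the bHLH partner of MYB factors in tannin and anthocyanin synthesis, was the 1 member that passed when adjusted over the list alone (limma, adjusted p = 0.0142), and none passed across all features. TT8 stood at 8.78 ± 0.61 (SD, n = 3) against 6.78 ± 0.28 (SD, n = 3), a log2 difference of 2.00 (SE 0.32) and at least 3.17-fold by the bound used for BAN. The other bHLH genes EGL3 and GL3 had 0.32 (SE 0.15) and 0.17 (SE 0.24), and the WD40 gene TTG1 had -0.05 (SE 0.11).

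Among the MYB genes of this list, MYB5 had a log2 difference of 0.64 (SE 0.15) and MYB4, a repressor of phenylpropanoid genes, 0.66 (SE 0.23). TT2, the endogenous MYB regulator of BAN in seeds, had -0.16 (SE 0.15) with both means in the low mode, at 5.22 and 5.37. The anthocyanin regulators PAP1, PAP2, MYB113 and MYB114 had -0.19 (SE 0.30), 0.53 (SE 0.29), 0.12 (SE 0.39) and 0.11 (SE 0.21), with PAP2 and MYB113 in the low mode. GL1 had 0.17 (SE 0.14), and MYBL2 had -0.51 (SE 0.42), a difference that came from MYBPAR replicate 2 at -1.52. The trichome and epidermis genes CPC, TRY, GL2 and TTG2 lay between 0.16 and 0.50, the seed coat genes TT1 and TT16 at -0.23 and -0.26 in the low mode, and the repressors LBD37, LBD38 and LBD39 between -0.32 and -0.07.

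Neighbouring pathways were not called by camera. The phenylpropanoid list had a median of 0.09 (adjusted p = 0.409) with 4CL3, a coumarate ligase tied to flavonoids, at 0.77 (SE 0.29). The shikimate and aromatic amino acid list had 15 of 18 members above 0 and a median of 0.07 (adjusted p = 0.107), with the arogenate dehydratase gene ADT3 at 0.28 (SE 0.10). The anthocyanin decoration list had a median of 0.05, a mean of -0.01 and a downward test direction (adjusted p = 0.920), with AT1G03495 at -0.18 (SE 0.14). The lignin and sinapate list had a median of 0.02, a mean just below 0 and an upward test direction (adjusted p = 0.920), with SNG1 at -0.31 (SE 0.18). The seed coat mucilage list had 0.02 (adjusted p = 0.877), with GATL5 at 0.18 (SE 0.12).

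Flower markers were called higher as a group and senescence genes lower, both with no member past the threshold. The flower list had 10 of 12 members above 0 and a median of 0.66 (camera, adjusted p = 0.0322; adjusted p = 0.690 with an estimated correlation), with the floral organ gene SEP1 at 0.74 (SE 0.24). The call was lost without empty vector replicate 1 (median 0.29, adjusted p = 0.331) and without MYBPAR replicate 2 or 3 (medians 0.51 and 0.42, adjusted p = 0.102 and 0.171). In the senescence list 0 of 5 members were above 0, and the median was -0.36 (camera, adjusted p = 0.00344; adjusted p = 0.534 with an estimated correlation), with SAG21 at -0.36 (SE 0.13). Without empty vector replicate 1 the median stayed at -0.34 but was not called (adjusted p = 0.114), and with the floral covariate it was -0.15 (adjusted p = 0.291).

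The remaining lists, which describe organ makeup and plant state, were not called over all 6 arrays. Root markers had a median of 0.20 (camera, adjusted p = 0.0728), and WOX5, a gene of the root stem cell niche, was the 1 member that passed when adjusted over the list alone (limma, adjusted p = 0.0467), with 0.48 (SE 0.12) and both means in the low mode. The root list was called without MYBPAR replicate 2 (median 0.26, adjusted p = 0.0305) and without empty vector replicate 2 (median 0.30, adjusted p = 0.0282), and its median was 0.12 without MYBPAR replicate 3. Root hair genes had 0.02 (adjusted p = 0.528; EXPA18 0.44, SE 0.29) and light signalling genes 0.12 (adjusted p = 0.482; COP1 0.11, SE 0.11). Photosynthesis genes had -0.06 (adjusted p = 0.482), with CAB2, a chlorophyll-binding protein gene, at -1.14 (SE 0.91), a difference that came from MYBPAR replicate 2 at -3.30. Salicylate defence genes had 0.23 (adjusted p = 0.482; PAD3 0.64, SE 0.19), jasmonate genes -0.36 (adjusted p = 0.152; JAZ5 -1.27, SE 0.54) and glucosinolate genes 0.04 (adjusted p = 0.482; CYP79F1 0.31, SE 0.14). The jasmonate list was called without MYBPAR replicate 2 (median -0.30, adjusted p = 0.00849), and its median was -0.20 without MYBPAR replicate 3 and -0.12 without empty vector replicate 3. JAZ5 stood between -1.88 and -0.76 when 1 sample was left out, the ends being without MYBPAR replicates 1 and 3. The salicylate defence median was -0.02 without empty vector replicate 2.

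Median and test direction differed in sign in 4 further lists near 0. Seed storage genes had a median of 0.04 with a downward test (adjusted p = 0.967; OLEO1 0.37, SE 0.31), and oxidative stress and heat genes a median of 0.02 and a mean of -0.12 (adjusted p = 0.849; HSP70 -0.71, SE 0.32). Phosphate starvation genes had a median of -0.01 and a mean of 0.10 (adjusted p = 0.482; SPX1 0.40, SE 0.13). The 8 housekeeping genes had a median of 0.01 with a downward test (adjusted p = 0.967), and AT4G34270 stood at 0.06 (SE 0.10).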

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

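The floral covariate, the clock covariate and the list without BAN, or without both BAN and AHA10, were chosen after seeing the data. The 2 features higher in the MYBPAR lines became 0 with no moderation, with the replicate block, with the floral covariate and with the clock covariate, and 0 to 3 when 1 replicate was left out (3 without MYBPAR replicate 1, and 0 without each of the other 5 samples). The other settings gave 2 or 3 calls, BAN and AT2G38900 among them except with log2(value + 32), which called AHA10 and BAN, and BAN was among the 2 smallest p-values in all 18 refits, with log2 differences of 5.08 to 6.49 and adjusted p of 0.00141 to 0.914. No setting called a feature lower. With fewer samples, a block or a covariate, fewer degrees of freedom remain; whether this alone ended the calls was not tested. The labels do not say whether equal replicate numbers share a batch. Deviations from the group means correlated across features at 0.30, -0.06 and 0.24 for numbers 1, 2 and 3. The highest value was 0.36, for MYBPAR replicate 3 with empty vector replicate 2, and MYBPAR replicate 2 correlated best with empty vector replicate 1. Deviations within a group sum to 0, so these values depend on each other and cannot decide whether the numbers pair the samples. With the replicate block 5 lists were called. The 5 called lists became 2 with array weights, 3 with the floral covariate, 10 with the clock covariate, 0 with an estimated correlation and 1 with fry, and 1 to 6 when 1 replicate was left out (1 without empty vector replicate 1); the cause was not tested. The clock covariate added the regulator, phenylpropanoid, root, jasmonate and glucosinolate lists. The proanthocyanidin branch was called in 20 of 21 settings, the list without both BAN and AHA10 not counted. The exception was camera with the estimated correlation (median 0.47, adjusted p = 0.105). For this list the estimate, -0.06, lay below the preset, so stronger correlation between its members does not account for the lost call. With the floral covariate the flower list median turned to -0.0202, as it holds the covariate's genes, the seed list to -0.14 (adjusted p = 0.0405) and the phosphate list to 0.35 (adjusted p = 0.0415), for which the cause was not tested. Low signal limits BAN, AT2G38900, GSTF5 and TT8, whose control values lie in the low mode.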

Other observations

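The position test, the test without 1 MYBPAR line, the tests of the construct and of a line-specific clock, the relations with the components, the count of splits for features, the covariate fits and the use of resampling intervals for the flavonol list were chosen after results were seen. The touch and cold list (CBF1, TCH4, STZ and 4 others) and the anther list were written after the genes at the ends of the first principal component had been looked at, and the clock was taken up after that component had been weighed. Between arrays the mean of the touch and cold list had an SD of 0.71 and that of the anther list 0.62, where the medians over 10000 random lists of matched expression were 0.06 and 0.10. The first component held 38.5% of the variance and did not separate the groups (means 20.1 and -20.1, exact permutation p = 0.3).

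Over the 6 arrays 8 relations with the first 2 components were computed. The genes were chosen after values and components had been seen, so their p-values describe the relations and do not test them independently. The floral organ identity mean correlated with the first component (Pearson's r = 0.93, exact permutation p = 0.00417, adjusted 0.0333; Spearman's rho = 0.94, p = 0.0167, adjusted 0.0667), and r was 0.85 without the 2 farthest arrays. The clock score correlated with the second component, which held 27.8% (r = 0.90, exact permutation p = 0.00972, adjusted 0.0389; rho = 0.83, p = 0.0583, adjusted 0.156), and r was 0.70 without the 2 farthest arrays. The touch and cold mean correlated negatively with the first component (r = -0.88, exact permutation p = 0.0278, adjusted 0.0741; rho = -0.94, p = 0.0167, adjusted 0.0667), and r was -0.53 without the 2 farthest arrays. For the other 5 relations the exact permutation p of Pearson's r was 0.139 or more: anther mean with the first (r = 0.70) and second component (r = 0.11), clock score with the first (r = -0.34), and floral mean (r = 0.12) and touch and cold mean (r = -0.05) with the second.

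CCA1, LHY and PRR9 were far lower in MYBPAR replicate 2 than on the other 5 arrays. Another time of day at harvest is a candidate explanation: the mean of 5 other morning genes (RVE8, RVE1, LNK1, CDF1 and COL2) in that sample differed by -1.17 from the lowest of the other arrays, and the mean of 4 other evening genes (PRR3, BOA, ELF3 and GRP8) was 12.72 against 10.07 to 12.31. In MYBPAR replicate 2, PRR3, BOA and ELF3 lay above all other arrays, but GRP8, at 14.01, lay within their range of 13.69 to 14.23. A changed clock in that line, whose score was -5.84, cannot be told apart from time of day with 1 array per line. An effect of the construct stays open too: the clock scores of MYBPAR replicates 1 and 3, 0.67 and -0.27, lay within the empty vector range of -2.22 to 2.51, but that these lines are not low is part of how the pattern was defined.

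BAN, AT2G38900, AHA10, GSTF5 and TT8 were higher in all 3 MYBPAR lines. They were weighed because they differed this way in the same data, so the tests below are not independent of that choice. More flower tissue is argued against as the whole cause, since with the floral covariate the lowest of the 5 lower 95% bounds was 1.03; the 2 calls ended (BAN 6.49, SE 0.37, from 6.21, SE 0.33; AT2G38900 6.10, SE 0.39, from 5.83, SE 0.34; both adjusted p = 0.116, against 0.00141 to 0.914 for BAN over all alternatives), with larger differences, larger errors and fewer degrees of freedom. For the array positions, only a steady gradient as the whole cause is argued against, since the MYBPAR arrays lie between the controls. The control at position 10 lay within 0.33 of the mean of those at positions 3 and 4 for all 5 genes. Genes chosen for such differences tend to have close control values, so this closeness is no independent test. Middle and end positions are confounded with the groups, and odd against even positions were not tested. More ovules or seed coats stay open: 8 such genes had a median log2 difference of 0.13 (SD over genes 0.36), under the smallest of the 5 changes, 1.42, but only 2 of the 8 lay above the low mode, so the bound set before the test was not one these genes could decide. An effect of the construct, found and tested on the same data, stays open beside it.

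The flavonol and early flavonoid lists were higher in the MYBPAR lines, with a flavonol median of 0.35, and none of 3 explanations was decided. The mark set for each was a fall to under 50% of that median. The floral covariate met it and the others did not, but resampling the list members gave intervals on both sides of 50%. These intervals vary the genes, whose estimated correlation was 0.50, and do not measure the spread between lines. More flower tissue may contribute: the median was 0.15 with the floral covariate (42.8% of the unadjusted value, 17.9% to 68.5%), and the call ended as the median shrank (adjusted p = 0.246). Time of day stays open, with a median of 0.21 under the clock covariate (59.9%, 34.2% to 106%; adjusted p = 0.00131) and an early flavonoid median of 0.33, not below its unadjusted 0.29, and so does MYBPAR replicate 2 alone, with 0.19 without it (53.7%, 34.8% to 91.6%; adjusted p = 0.00281). Over all alternatives the adjusted p of the flavonol list ran from 3.49e-06 to 0.534. An effect of the construct also stays open.

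The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2 features and the highest other split 30, and 3 of the 10 splits gave as many as the real one. Of the 4 splits that put MYBPAR replicate 1 with empty vector replicate 1, those that added empty vector replicate 3 or MYBPAR replicate 2 gave 30 and 25 features, and those that added MYBPAR replicate 3 or empty vector replicate 2 gave 0. Counts several times the real one point to a structure of the samples other than the groups. The split with 30 features parts the 3 arrays with the lowest floral organ identity means from the other 3 and called the flower list. The split with 25 called 0 lists and parts the odd array positions, 3, 5 and 7, from the even ones, 4, 8 and 10. It had 4102 features at an unadjusted p under 0.05 (limma), against 1602 in the real split. An effect of position is a candidate and was not tested. Odd and even positions are not balanced over the groups. For lists the real split gave 5 and the highest other 7, and 3 of the 10 splits gave as many. The proanthocyanidin list was called in the real split alone. Its members BAN and AHA10 part by the real groups, so a split that mixes the groups turns their differences into spread. The absence of the call in the other splits is therefore no independent test of this list. The early flavonoid, flavonol, flower and senescence lists were also called in other splits.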
